A study of Mus musculus with 41 samples.

How the data were processed

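RNA was measured in 41 single mouse embryos of the C57BL6/J strain at the 2-cell stage, each amplified and made into a library with the SMART-Seq stranded kit and read on a NextSeq2000 as 61-base pairs, per the labels' protocols. Wild-type (WT) embryos were collected at 32 h (WT early, n = 8) and at 48 h (WT late, n = 6) after the injection of human chorionic gonadotropin (hCG). Embryos of crosses between heterozygous carriers of a guide-RNA-made Duxbl knockout were collected at 48 h and were labelled either knockout (Duxbl-KO, n = 5) or a joint class of wild-type and heterozygous embryos (Duxbl-WT/Het, n = 22), in which the labels do not tell the genotypes apart. Each replicate is a single embryo. Nothing says that embryos of a group came from separate litters, so p-values measure the spread between these embryos, which may in part be technical.

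The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.10a, Picard 2.27.1, featureCounts 2.0.2, DESeq2 1.30.1 and DESeq, and the mouse build mm39. The role of each tool, the annotation release, whether strand was used in counting and how reads with several placements were treated are not given in the sources used here. A single table, which lists 36385 genes in 41 libraries, was used. The deposited values are a score per gene, not raw counts. In 29 libraries the low values skip whole numbers at a step between 1.12 and 1.95, the trace of counts divided by a factor per library and rounded to whole numbers, and in 12 libraries no step could be found. These 12 were all 8 WT early libraries and, for the rest, Duxbl-WT/Het libraries. Steps below 1 were not searched, so the depth of these libraries is unknown. Because rounding removed the fractions, whole reads could not be recovered. Dividing the totals by the step gave an estimate of 1168273 to 2691057 reads in those 29 libraries. Totals are called normalised reads here. Gene positions are those of the table on mm39, counted from 1; the reference annotation at hand was of build GRCm38, had the same start and end for 769 of 35370 shared genes and was not used for positions. The table had 530 repeated gene symbols, 194 genes at 0 in every library, no pair of identical libraries and no mitochondrially encoded gene, so the mitochondrial list had 0 members.

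The tests had been fixed for raw counts before the data were examined, with a count model. Since the values proved to be normalised, limma 3.58.1 in R 4.3.3 was used in its place, chosen from the unit and before any test result was seen. Values were turned into CPM, counts scaled to a common library total, from the normalised reads, scaled by trimmed means of M values (TMM, trimming 30% of the ratios and 5% of the levels) computed within each comparison, so the CPM of a group can differ slightly between comparisons. The log2 of CPM plus a pseudocount of 1 was fitted with an intensity trend in the empirical Bayes step. Fold changes are therefore on the log2(CPM + 1) scale, which understates changes of low genes. A gene was tested when it reached 10 normalised reads at the median library total, which was 3.02 CPM in the stage comparison and 3.69, 3.71 and 4.39 CPM in the comparisons of Duxbl-KO with Duxbl-WT/Het, of Duxbl-WT/Het with WT late and of Duxbl-KO with WT late. It had to do so in at least as many libraries as the smaller group holds (6 or 5), with a sum of at least 15. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and all adjusted p-values for genes come from limma with Benjamini-Hochberg adjustment.

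Comparisons were WT late with WT early, Duxbl-KO with Duxbl-WT/Het, Duxbl-WT/Het with WT late, and Duxbl-KO with WT late, each fitted on its own groups only. The named genes followed a rule written before the data were examined: Duxbl and Dux family members came first. Then came the 10 largest rises and falls among called genes with at least 10 CPM in the higher group (5 each way for the last comparisons), leaving out predicted or clone-named genes. Up to 4 members with the smallest adjusted p of each list with at least 5 tested members were added. There were 18 lists, fixed at the same time. They held Duxbl and Dux homeobox genes, 2-cell genes, PRD-like and Obox homeobox genes, pluripotency genes, maternal oocyte transcripts, and trophectoderm and primitive endoderm markers. Others held ribosome biogenesis genes, ribosomal protein genes, mitochondrially encoded proteins and replication-dependent histones. The rest held DNA replication, G2 and mitosis, p53 targets and DNA damage, stress and heat shock, chromatin silencing, and markers of other cells: cumulus and granulosa cells, sperm, and blood and oviduct epithelium. Lists with at least 5 tested members were described, and lists with fewer are given by their members. List tests used camera, two-sided, with a preset correlation of 0.01, and again with an estimated correlation, adjusted by Benjamini-Hochberg over the lists of a comparison. Fry was run beside it.

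A stage index was computed per embryo as the mean log2 level of 2947 genes higher in WT late than in WT early embryos minus that of 2694 genes lower in them, and compared by exact two-sided permutation tests. Summed levels of the members of multicopy gene families were compared in the same way. The fits were tested on simulated data with 2-fold and 4-fold changes in known genes. In the stage comparison 94.0% of the 2-fold and 100% of the 4-fold genes were called. In Duxbl-KO against Duxbl-WT/Het these were 63.0% and 97.0%, in Duxbl-WT/Het against WT late 61.0% and 98.9%, and in Duxbl-KO against WT late 20.8% and 86.6%. The share of calls that were unchanged genes was 6.73%, 3.61%, 4.35% and 7.14% in the same order. The simulated spread came from the second-named group of each comparison alone, which for stages was WT early, the group with the closest replicates. At most 200 tested genes were changed, against 9105 genes called between stages. These rates therefore hold for the simulated setting and may be better than those in the real data.

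Alternatives were other scalings (median of ratios, totals only, and the scaling as deposited), pseudocounts of 0.25 and 4 CPM, no filter and a stricter filter of 5 CPM. Further ones were all 4 groups in a single fit, a 2-fold minimum, the replicate number as a block, robust empirical Bayes, array quality weights, no genes of chromosomes X and Y, and leaving out each library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the R package data.table (version 1.17.8), were also used. Many 2-cell genes are members of families of near-identical copies, and reads from them may be split between copies or dropped by the counting, so values of single copies are uncertain.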

Results

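Transcripts were measured in 41 single mouse embryos at the 2-cell stage, when the embryo's own genome is first switched on. WT embryos were taken early (32 h after hCG, n = 8) and late (48 h, n = 6). Offspring of heterozygous Duxbl carriers were taken at 48 h and were either Duxbl-KO (n = 5) or Duxbl-WT/Het (n = 22, wild-type and heterozygous embryos together). Totals ran from 3222727 to 3657356 normalised reads in WT early and 2049231 to 2828104 in WT late embryos. They ran from 2163117 to 3013042 in Duxbl-KO and 2137713 to 3001986 in Duxbl-WT/Het embryos. Between 18820 and 24116 genes lay above 0 in an embryo. Where reads could be estimated, their median was 1617395 in WT late (6 libraries), 1451318 in Duxbl-KO (5) and 2199515 in Duxbl-WT/Het embryos (18). Embryos of a group ranked genes alike, with a median Spearman correlation between replicates of 0.982 in WT early, 0.897 in WT late, 0.922 in Duxbl-KO and 0.924 in Duxbl-WT/Het embryos across 11391 genes.

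Duxbl1, the Duxbl gene of the table (ENSMUSG00000048502, chromosome 14, 25979001 to 25990512, mm39), encodes a homeobox protein related to Dux and was reduced, not lost, in every embryo labelled knockout. It stood at 27.3 ± 8.63 CPM (SD, n = 5) in Duxbl-KO embryos, range 16.7 to 35.2, against 163 ± 38.8 CPM (n = 22), range 103 to 240, in Duxbl-WT/Het embryos. WT late embryos held 146 ± 41.01 CPM (n = 6) and WT early embryos 146 ± 16.7 CPM (n = 8). The knockout difference was a log2 fold change of -2.58 (SE 0.18, limma adjusted p = 2.2e-11) against Duxbl-WT/Het and -2.45 (SE 0.25, limma adjusted p = 1.2e-05) against WT late embryos. Duxbl-WT/Het and WT late embryos differed by 0.17 (limma adjusted p = 0.389), and WT late and WT early by -0.05 (SE 0.14, limma adjusted p = 0.747), with a sign that turned under other scalings. How the guide RNA changed the gene is not given in the sources used here, so the source of the remaining level cannot be told. Reads from outside a changed part may add to it, which was not tested. Duxf3, the mouse Dux gene that acts at genome activation, was too low to test, at 2.43 ± 1.55 CPM in WT early (n = 8), 0.89 ± 0.73 in WT late (n = 6), 0.31 ± 0.42 in Duxbl-WT/Het (n = 22) and 0.23 ± 0.51 in Duxbl-KO embryos (n = 5).

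**Figure D1:**
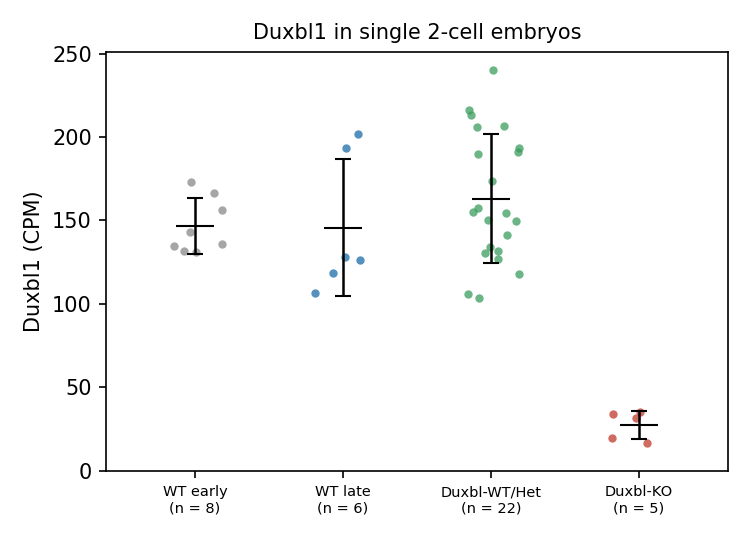
Duxbl1 in CPM (vertical axis) in single embryos of the 4 groups, with dots for embryos and bars for the mean ± SD. The Duxbl-KO embryos lie between 16.7 and 35.2 CPM and the Duxbl-WT/Het embryos between 103 and 240 CPM.

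The stage comparison asked what changes in WT embryos between early and late 2-cell. Genes that were low at the early point rose many-fold, among them Slc34a2, a sodium phosphate cotransporter (chromosome 5, 53195423 to 53229006), from 4.21 ± 1.85 CPM (n = 8) to 633 ± 317 CPM (n = 6). Ficd, an endoplasmic reticulum enzyme that modifies the chaperone BiP, rose from 1.92 ± 0.67 to 296 ± 79.4 CPM and Hipk1, a nuclear kinase, from 7.22 ± 1.96 to 834 ± 330 CPM. Oocyte transcripts fell, such as Nlrp9b (799 ± 81.5 to 67.5 ± 17.9 CPM). Also lower were Neil3, a DNA glycosylase (294 ± 26.8 to 18.05 ± 5.21 CPM), and Rgs2, a regulator of G-protein signalling (677 ± 134 to 51.1 ± 32.1 CPM). The log2 fold changes were 6.76 (SE 0.35, limma adjusted p = 1.1e-12) for Slc34a2, 6.65 (SE 0.22, 4.8e-15) for Ficd and 6.59 (SE 0.24, 1.5e-14) for Hipk1. They were -3.99 (SE 0.15, limma adjusted p = 2.5e-14) for Neil3 and -3.91 (SE 0.27, 6.9e-11) for Rgs2. The other large rises were Sp6, Tdpoz4, Ubtfl1, Exoc3l2, Mt1, Trim43b and Zscan5b, with log2 fold changes from 6.63 for Sp6 to 6.27 for Zscan5b. The other large falls were Fam90a1a (-4.51), Eps8l3 (-4.38), Pja1 (-4.10), Obi1 (-3.93), Ifit1bl2 (-3.86), Ftdc1 (-3.84), Gspt2 (-3.80) and Mmut (-3.75). Of predicted or clone-named genes, 9 with larger rises and 2 with larger falls were left out.

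Of 33 tested 2-cell genes, known for their burst of expression at genome activation, 30 rose and 2 fell in WT late embryos, and 30 and 2 adjusted over the list alone. Their median log2 fold change was 4.06 (camera adjusted p = 7.9e-12, adjusted p = 0.112 with an estimated correlation). Tdpoz4 stood at 112 ± 37.8 against 0.16 ± 0.24 CPM and Trim43b at 140 ± 47.5 against 0.78 ± 0.72 CPM. Of 55 maternal transcripts, 47 fell and 2 rose (47 and 2 adjusted over the list alone). The median was -1.75 (camera adjusted p = 8.0e-10, adjusted p = 0.261 with an estimated correlation). Nlrp9b (-3.59), Nlrp4a (-3.05), which are oocyte members of the Nlrp family, Oas1d (-2.83) and Fbxw28 (-3.17) had the smallest adjusted p of this group by limma. Ribosomal protein genes rose in 57 of 72 cases and fell in 2, the same numbers adjusted over the list alone. The median was 1.37 (camera adjusted p = 4.9e-10, adjusted p = 0.261 with an estimated correlation). Rplp1 went from 6.64 ± 1.25 to 156 ± 72.0 CPM and Rps3 from 2.85 ± 1.07 to 55.0 ± 9.85 CPM. Of 50 ribosome biogenesis genes 28 rose and 7 fell, both over all genes and adjusted over the list alone, among the rises Nop16 (5.55) and Polr1b (2.88), a subunit of RNA polymerase I. The median was 0.83 (camera adjusted p = 6.6e-04, adjusted p = 0.491 with an estimated correlation).

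Pluripotency genes rose in 12 and fell in 5 of 19 cases (the same adjusted over the list alone), among them Klf5 (4.74), Fbxo15 (4.13), Tbx3 (3.49) and Klf4 (2.98). The median was 1.69 (camera adjusted p = 0.0040, adjusted p = 0.171 with an estimated correlation). Stress and heat shock genes rose in 13 and fell in 2 of 17 cases, both ways of adjusting (over all genes and adjusted over the list alone), with the co-chaperone Bag3 (5.03) and Dnajb9 (4.20). The median was 1.68 (camera adjusted p = 0.0021, adjusted p = 0.243 with an estimated correlation). Of 24 p53 and DNA damage genes 17 rose and 5 fell (17 and 5 adjusted over the list alone), among them Sesn2 (5.24) and Cdkn1a (3.44), the cell cycle inhibitor p21. The median was 1.45 (camera adjusted p = 0.0061, adjusted p = 0.171 with an estimated correlation). Replication-dependent histones rose in 26 and fell in 3 of 39 cases (26 and 3 adjusted over the list alone), with H1f5 at 3.39 and H2ac20 at 3.24. The median was 0.79 (camera adjusted p = 6.1e-04, adjusted p = 0.243 with an estimated correlation). DNA replication genes fell in 20 and rose in 4 of 33 cases (21 and 4 adjusted over the list alone). The median was -0.72 (camera adjusted p = 0.0256, adjusted p = 0.261 with an estimated correlation). Slbp, which binds histone mRNA, fell (-2.36), while Ccne1, cyclin E1, rose from 7.08 ± 1.51 to 400 ± 115 CPM.

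The remaining lists were not called by camera in the stage comparison. Of 34 G2 and mitosis genes 21 fell and 10 rose (the same adjusted over the list alone; camera adjusted p = 0.0548), with Pttg1, securin, at -2.22 and Cdc25c at 3.88. Chromatin silencing genes split 11 higher and 19 lower of 38 (12 and 19 adjusted over the list alone; camera adjusted p = 0.267). Zfp57, a zinc finger protein that guards imprints, fell from 3411 ± 167 to 496 ± 85.0 CPM and Hdac1 rose from 6.91 ± 1.61 to 137 ± 46.2 CPM. Obox and PRD-like homeobox genes split 4 higher and 5 lower of 9 (4 and 5 adjusted over the list alone), with Obox6 at 124 ± 61.0 against 0.58 ± 0.48 CPM. Their median was -0.93 while their mean was 1.35, and camera pointed up (adjusted p = 0.800). Trophectoderm and primitive endoderm markers split 5 higher and 3 lower of 10 (5 and 3 adjusted over the list alone; camera adjusted p = 0.206), with Gata2 (4.23) and Eomes (2.92) in front. Of the markers of other cells, the cumulus gene Cyp19a1 fell (-2.42, limma adjusted p = 1.0e-07), Odf2 of the sperm list did not pass (-0.27, limma adjusted p = 0.162) and Epcam of the blood and oviduct list rose (4.74, limma adjusted p = 3.4e-11).

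In all, 9105 of 12346 tested genes differed between stages by limma at a Benjamini-Hochberg adjusted p under 0.05, 4058 higher and 5047 lower in WT late embryos. Without a further scaling of the deposited values the split was 3308 higher and 6269 lower, and it turned to 4784 higher and 4221 lower with totals only and to 6640 higher and 6010 lower with no filter. The median over all genes was -0.17 with TMM, -0.48 with the values as deposited, 0.07 with totals only and -0.07 with median-of-ratios scaling, and fold changes near those values depend on the scaling.

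The knockout comparison set Duxbl-KO against Duxbl-WT/Het embryos of the same kind of cross, at the same hour, and asked what the loss of Duxbl does to late 2-cell transcription. Genes of the 2-cell burst were higher in Duxbl-KO embryos. Zscan4c, of the Zscan4 family that marks the 2-cell embryo (chromosome 7, 10739672 to 10744474), stood at 90.1 ± 46.4 CPM (n = 5) against 8.51 ± 14.3 CPM (n = 22), and Zscan4b at 47.0 ± 15.3 against 3.45 ± 6.15 CPM. Eif4a3l1, a relative of the RNA helicase Eif4a3 (chromosome 6, 136304537 to 136306981), stood at 180 ± 87.2 against 15.2 ± 26.8 CPM, and Eif1ad7, of a multicopy family named after the initiation factor 1A domain, at 268 ± 19.1 against 32.5 ± 38.2 CPM. Lower were Nt5c, a nucleotidase, at 0.32 ± 0.54 against 13.9 ± 12.3 CPM, and Cmtm4, a membrane protein gene, at 15.1 ± 13.7 against 83.1 ± 35.5 CPM.

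Their log2 fold changes were 4.28 (SE 0.64, limma adjusted p = 3.6e-05) for Eif4a3l1, 3.88 (SE 0.47, 2.0e-06) for Zscan4b, 3.65 (SE 0.48, 5.7e-06) for Zscan4c and 3.52 (SE 0.47, 6.3e-06) for Eif1ad7. They were -3.05 (SE 0.54, limma adjusted p = 2.9e-04) for Nt5c and -2.56 (SE 0.37, 2.5e-05) for Cmtm4. The other large rises were Eif1ad10 (4.11), Eif1ad4 (3.74), Eif1ad15 (3.74), Pramel19 (3.67), H2-M10.4 (3.57) and Eif1ad3 (3.52). The other large falls were Plekhm2 (-2.88), B4galnt1 (-2.85), Nipal1 (-2.63), Bcl7a (-2.62), Slamf7 (-2.61) and Ripor3 (-2.59). Of predicted or clone-named genes, 8 with larger rises and 3 with larger falls were left out. Kcnk18, a potassium channel gene, was listed at 0 in all 5 Duxbl-KO embryos and in 8 of 22 Duxbl-WT/Het embryos, and its call (limma adjusted p = 0.043) was lost when any 1 of the 5 Duxbl-KO embryos was left out (limma adjusted p = 0.0703 to 0.0948). It was also lost without Duxbl-WT/Het replicate 1, 2, 3, 4, 6, 10, 12, 15, 17, 19 or 20 (limma adjusted p = 0.0522 to 0.0554), with no filter (0.0823) and with robust empirical Bayes (0.0551).

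Of 37 tested 2-cell genes, 26 were higher and 0 lower in Duxbl-KO embryos (27 and 0 adjusted over the list alone), by a median of 1.98. The list was called by camera (adjusted p = 2.0e-23) and also with an estimated correlation (adjusted p = 0.020). Tmem92 stood at 266 ± 48.6 against 51.6 ± 42.1 CPM (2.58, limma adjusted p = 3.1e-06) and Zscan4d at 101 ± 32.0 against 21.3 ± 10.9 CPM (2.24, limma adjusted p = 6.2e-07). The mean level of the list, as log2(CPM + 1), was 1.77 ± 0.35 in WT early, 4.69 ± 0.54 in Duxbl-WT/Het and 6.39 ± 0.16 in Duxbl-KO embryos, and in WT late embryos it ranged from 5.12 to 5.87. Replication-dependent histones were higher in 4 and lower in 0 of 50 cases (3 and 0 adjusted over the list alone), with H2bc14 at 1.42 and H4c2 at 1.03. The median was 0.41 (camera adjusted p = 9.6e-07, adjusted p = 0.845 with an estimated correlation). Ribosomal protein genes were lower in 9 and higher in 0 of 76 cases (6 and 0 adjusted over the list alone), among them Rpl14 (-1.22) and Rpl22 (-0.81). The median was -0.33 (camera adjusted p = 5.5e-06, adjusted p = 0.845 with an estimated correlation).

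**Figure D2:**
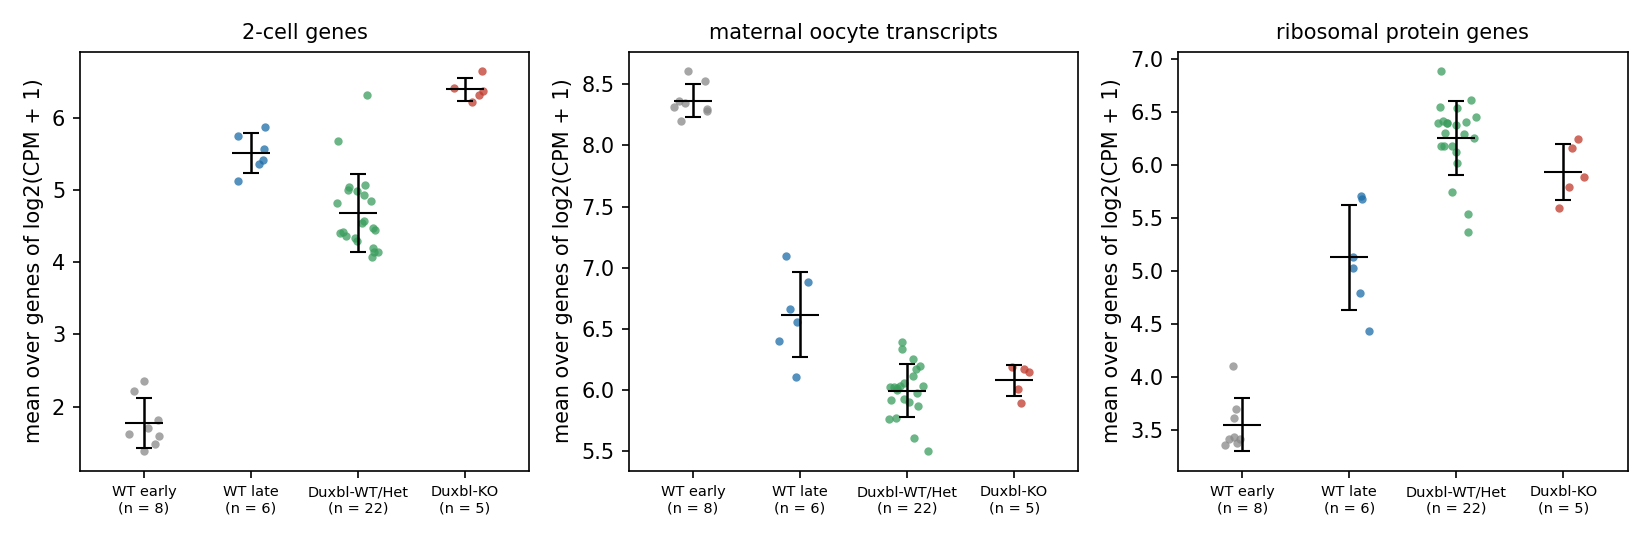
Mean over list genes of log2(CPM + 1) (vertical axis) per embryo for 2-cell genes, maternal oocyte transcripts and ribosomal protein genes in the 4 groups, with dots for embryos and bars for the mean ± SD. For 2-cell genes the Duxbl-KO embryos lie between 6.22 and 6.65 (SD 0.16, n = 5) and the Duxbl-WT/Het embryos between 4.07 and 6.32 (SD 0.54, n = 22).

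No other list was called in the knockout comparison, though single members passed. Of 9 Obox and PRD-like genes, Obox3 rose (195 ± 38.6 against 77.8 ± 41.1 CPM, limma adjusted p = 0.0017), so 1 was higher and 0 lower over all genes and 2 and 2 adjusted over the list alone. Their median was -0.04, their mean 0.11, and camera pointed up (adjusted p = 0.717). Of 21 pluripotency genes 1 was higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.717). The Krüppel-like factor Klf2 stood at 9.75 ± 3.38 against 39.1 ± 18.1 CPM (-1.79, limma adjusted p = 6.3e-04), with Fgf4 at -0.95 and Zfp42 at 1.11. Maternal transcripts were higher in 1 and lower in 0 of 54 cases (0 and 0 adjusted over the list alone; camera adjusted p = 0.431). Of 12 trophectoderm and primitive endoderm markers 0 were higher and 2 lower (the same adjusted over the list alone; median 0.22, mean -0.05, camera up, adjusted p = 0.870). Tead4, a trophectoderm transcription factor, stood at 23.0 ± 5.08 against 104 ± 52.6 CPM (-1.92, limma adjusted p = 0.0020), and Gata4 (-0.56). Stress genes were higher in 4 and lower in 0 of 19 cases (4 and 1 adjusted over the list alone; camera adjusted p = 0.225). The 4 were Ppp1r15a (0.75), Ddit3 (1.29), Hspa1a (1.18) and Hspa1b (1.10). Chromatin silencing genes were higher in 3 and lower in 4 of 38 cases (3 and 10 adjusted over the list alone; camera adjusted p = 0.225), with the histone methyltransferase subunit Ehmt1 (-1.39) and the demethylase Kdm1a (-1.13) lower.

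Ribosome biogenesis genes were higher in 1 and lower in 2 of 50 cases (1 and 1 adjusted over the list alone; camera adjusted p = 0.111), with Polr1a at -1.20. Of 33 DNA replication genes 1 was higher, Lig1 (1.82), and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.578). Of 34 G2 and mitosis genes 2 were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.717), with Fbxo5 at 1.10 and Kif11 at -0.69. Of 24 p53 and DNA damage genes 1 was higher, Btg2 (1.63), and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.638). No marker of cumulus cells, sperm, blood or oviduct passed in this comparison, with Tnfaip6 at 0.60, Odf2 at 0.04 and Epcam at -0.16 by limma.

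Sums over the members of multicopy families, chosen after their values were seen, were higher in Duxbl-KO embryos for 5 of 7 families. No preset list names Eif1ad, and several of its members were among the largest rises of this same comparison. The p-values of the sums do not account for that choice and only describe these embryos. The 9 Zscan4 copies summed to 509 ± 251 CPM in Duxbl-KO (n = 5), 88.2 ± 72.8 in Duxbl-WT/Het (n = 22), 174 ± 55.6 in WT late (n = 6) and 28.0 ± 10.2 in WT early embryos (n = 8). The 17 Eif1ad copies summed to 1316 ± 241 CPM in Duxbl-KO, 168 ± 161 in Duxbl-WT/Het and 286 ± 104 in WT late embryos. Against Duxbl-WT/Het, the log2 difference was 2.60 for Zscan4 (exact permutation p = 2.5e-05, adjusted 5.8e-05 over 7 families) and 3.29 for Eif1ad (exact permutation p = 1.2e-05, the smallest that 80730 splits can give, adjusted 4.3e-05). Against WT late embryos it was 1.47 for Zscan4 (exact permutation p = 0.0065, adjusted 0.0152) and 2.25 for Eif1ad (exact permutation p = 0.0022, the smallest that 462 splits can give, adjusted 0.0076). Usp17l (0.74), Tcstv (0.88), Tdpoz (0.50) and Trim43 (1.11) were also higher than in WT late embryos, with adjusted exact permutation p-values of at most 0.0480, and Obox did not pass (-0.12, adjusted exact permutation p = 0.476). For Trim43 the sums were 562 CPM in Duxbl-KO and 557 CPM in Duxbl-WT/Het embryos. Usp17l (2.07), Tcstv (2.30) and Tdpoz (0.99) sums were also higher in Duxbl-KO than in Duxbl-WT/Het embryos, with adjusted exact permutation p-values of at most 5.0e-04. Trim43 did not pass (0.01, adjusted exact permutation p = 0.925, sign turned by other scalings), nor did Obox (0.17, adjusted exact permutation p = 0.121). Obox members did not move together. In WT early embryos Obox3, Obox6 and Obox8 stood at 0.47, 0.58 and 0.16 CPM, while the Obox sum was 2191 CPM. The sum can therefore hide single members, such as Obox3, which was higher in Duxbl-KO embryos by limma.

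**Figure D3:**
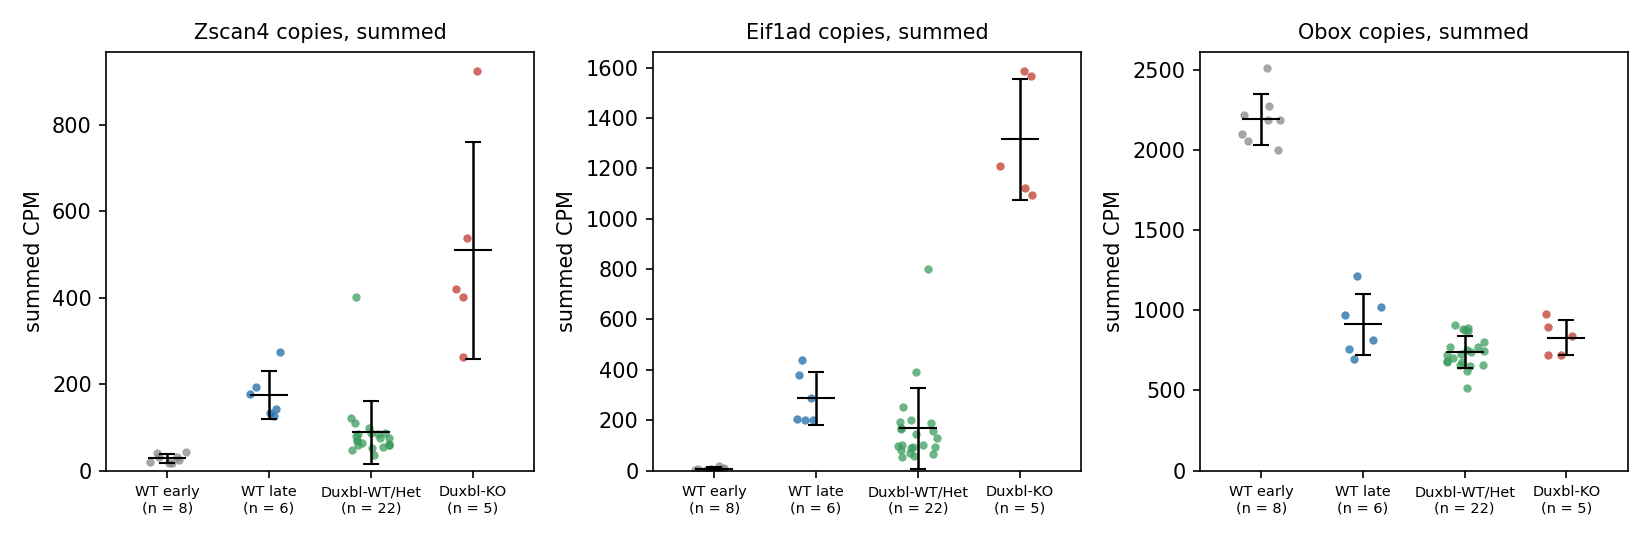
Summed CPM (vertical axis) of the Zscan4, Eif1ad and Obox copies per embryo in the 4 groups, with dots for embryos and bars for the mean ± SD. All 5 Duxbl-KO embryos lie above all Duxbl-WT/Het embryos for Eif1ad (at least 1095 CPM against at most 800 CPM), 4 of 5 do for Zscan4, and 1 does for Obox.

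By limma with Benjamini-Hochberg adjustment 1931 of 13728 genes differed between Duxbl-KO and Duxbl-WT/Het embryos, 749 higher and 1182 lower in Duxbl-KO. The split was 612 higher and 1405 lower with the values as deposited, 851 and 983 with median-of-ratios scaling, and it turned to 984 higher and 862 lower with no filter. The count dropped to 1166, 1229 and 1183 without Duxbl-KO replicates 2, 3 and 4, and to 1065 (515 higher, 550 lower) with a 2-fold minimum. It was 3108 (1107 higher, 2001 lower) with array quality weights.

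A stage index placed each embryo on the WT early-to-late axis, to ask whether knockout embryos lie at another point of it. Duxbl-KO embryos stood at 0.99 ± 0.15 (n = 5), Duxbl-WT/Het at 0.80 ± 0.24 (n = 22), WT late at 0.54 ± 0.48 (n = 6) and WT early at -3.68 ± 0.14 (n = 8). The difference of 0.18 between Duxbl-KO and Duxbl-WT/Het embryos did not pass (exact permutation p = 0.119, adjusted 0.119). Neither did 0.45 between Duxbl-KO and WT late (exact permutation p = 0.0801, adjusted 0.119) nor 0.26 between Duxbl-WT/Het and WT late embryos (exact permutation p = 0.0675, adjusted 0.119). The WT late embryos had helped to choose the index genes, so the differences from WT late may be biased and decide nothing. No crossed embryo took part in that choice. With the 200 strongest stage genes each way, the Duxbl-KO difference from Duxbl-WT/Het was 0.34 (exact permutation p = 0.0231). The 200 rising genes included 2-cell genes such as Tdpoz4 and Trim43b, and this shorter index was not run without them. Its difference therefore cannot tell stage from the rise of the 2-cell list. Across 11437 genes, which are not independent replicates, the stage and knockout log2 fold changes had a Pearson r of 0.16 and a Spearman rho of 0.07, and 37 of 100 drawn splits of the crossed embryos, the real one included, gave an absolute r as large.

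**Figure D4:**
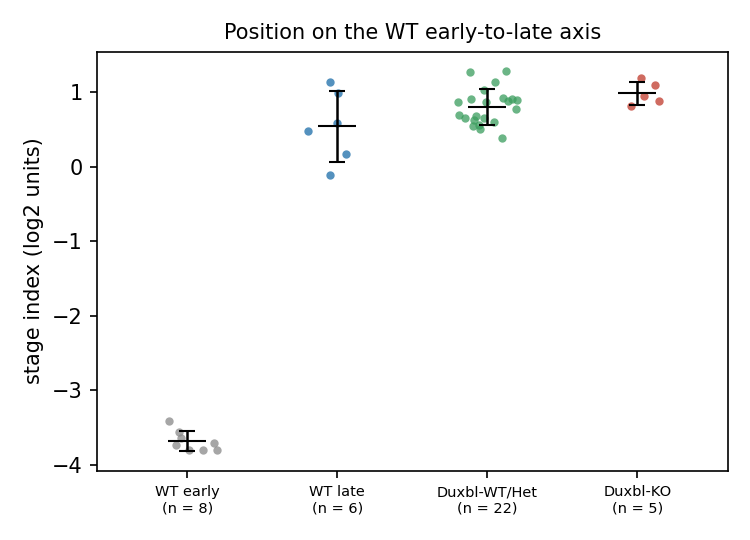
Stage index in log2 units (vertical axis) per embryo in the 4 groups, with dots for embryos and bars for the mean ± SD. The 3 late groups overlap, with Duxbl-KO embryos between 0.82 and 1.19 and Duxbl-WT/Het embryos between 0.39 and 1.29.

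Duxbl-WT/Het embryos were set against WT late embryos as the background that any comparison across the crosses carries. Cacna1s, a calcium channel subunit (chromosome 1, 135980488 to 136047560), stood at 0.040 ± 0.13 CPM (n = 22) against 155 ± 36.8 CPM (n = 6), and Pramel27, of the PRAME-like family (chromosome 4, 143573067 to 143580207), at 0.035 ± 0.11 against 69.8 ± 20.6 CPM. The opposite held for Colgalt2, a collagen galactosyltransferase (chromosome 1, 152275581 to 152386446), listed at 0 in all 6 WT late embryos and at 35.6 ± 19.2 CPM in Duxbl-WT/Het embryos. Chl1 (14.6 ± 4.45 CPM) and Adcy2 (16.8 ± 9.95 CPM) were also listed at 0 in all WT late embryos. Log2 fold changes were -7.21 (SE 0.19, limma adjusted p = 2.6e-25) for Cacna1s and -6.04 (SE 0.20, 7.4e-22) for Pramel27. Next came Pdgfrl (-3.84), Mycn (-3.81) and Arsk (-3.78) among falls and by Rps3a3 (3.65) and Chit1 (3.62) among rises. Of predicted or clone-named genes, 2 with larger falls were left out.

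**Figure D5:**
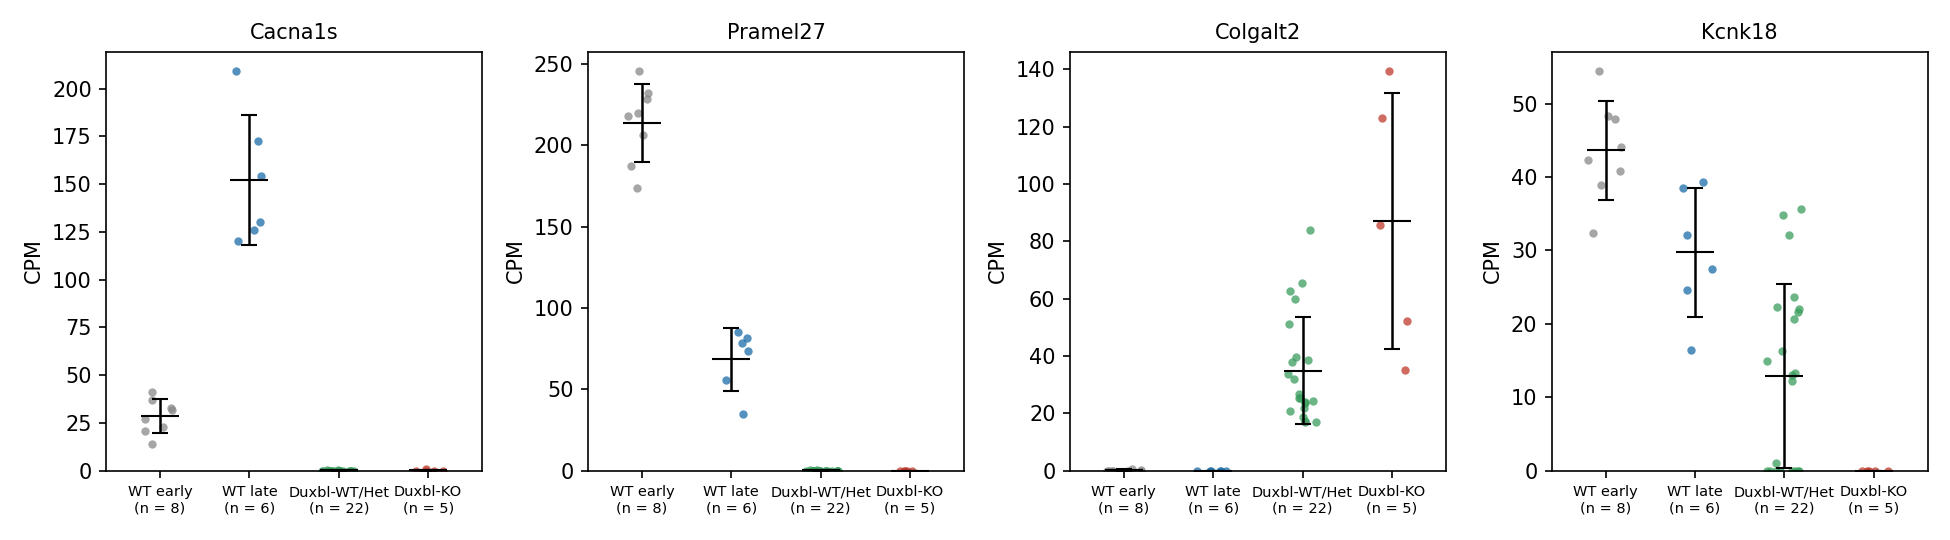
CPM (vertical axes) of Cacna1s, Pramel27, Colgalt2 and Kcnk18 per embryo in the 4 groups, with dots for embryos and bars for the mean ± SD. No crossed embryo exceeds 0.68 CPM for Cacna1s, where WT late embryos lie between 120 and 209 CPM, and Colgalt2 is listed at 0 in every WT late embryo.

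Ribosomal protein genes were higher in 72 and lower in 0 of 76 cases in Duxbl-WT/Het embryos (74 and 0 adjusted over the list alone). The median was 1.07 (camera adjusted p = 7.1e-20, adjusted p = 0.363 with an estimated correlation). Rps20 stood at 66.5 ± 17.7 against 17.1 ± 8.83 CPM. Ribosome biogenesis genes were higher in 47 and lower in 0 of 50 cases (the same adjusted over the list alone). The median was 1.13 (camera adjusted p = 1.3e-14, adjusted p = 0.363 with an estimated correlation), with the nucleolar genes Nolc1 (1.31) and Gnl3 (1.63). Maternal transcripts were lower in 36 and higher in 3 of 54 cases (36 and 3 adjusted over the list alone). The median was -0.60 (camera adjusted p = 2.9e-08, adjusted p = 0.363 with an estimated correlation), with Btg4, an adaptor for the removal of maternal mRNA, at 672 ± 196 against 1734 ± 703 CPM. Of 36 2-cell genes 20 were lower and 7 higher (21 and 7 adjusted over the list alone). The median was -1.19 (camera adjusted p = 0.0039, adjusted p = 0.481 with an estimated correlation), with Usp17le (-2.85) and Zscan4d (-1.26) lower and Trim43c (1.84) higher. G2 and mitosis genes were higher in 17 and lower in 3 of 34 cases (the same adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.0352, adjusted p = 0.481 with an estimated correlation). Cenpe stood at 1.09 and Wee2, an oocyte kinase, at -1.76.

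Camera called no other list between Duxbl-WT/Het and WT late embryos, and where no further count is given the counts were the same adjusted over the list alone. DNA replication genes were higher in 16 and lower in 5 of 34 cases (camera adjusted p = 0.0754), with Gins3 at 3.26. Trophectoderm and primitive endoderm markers were higher in 3 and lower in 8 of 13 (camera adjusted p = 0.0773). Tead4 stood at 105 ± 53.5 against 10.4 ± 9.57 CPM and Gata2 at -2.98. Pluripotency genes were higher in 8 and lower in 6 of 21 cases (9 and 7 adjusted over the list alone; camera adjusted p = 0.699). Sox2 stood at 4.93 ± 6.36 against 36.0 ± 13.9 CPM and Dppa2 at 1.49. Obox and PRD-like genes were higher in 4 and lower in 4 of 9 (median -0.21, mean 0.04, camera down, adjusted p = 0.909). Histones were higher in 3 and lower in 7 of 49 (2 and 5 adjusted over the list alone; median 0.16, mean -0.01, camera down, adjusted p = 0.527). Chromatin silencing genes were higher in 13 and lower in 5 of 38 (camera adjusted p = 0.225), with the heterochromatin protein Cbx1 at -2.05. Stress genes were higher in 4 and lower in 3 of 18 (median 0.06, mean -0.08, camera down, adjusted p = 0.909). Genes of the p53 list were higher in 6 and lower in 7 of 24 (camera adjusted p = 0.527), with Apaf1 at 1.86 and Mdm4 at -0.84. Among markers of other cells Epcam was higher (1.21, limma adjusted p = 3.7e-05) and Odf2 lower (-0.96, limma adjusted p = 1.1e-04), and Tnfaip6, the only tested cumulus marker, did not pass (-1.01, limma adjusted p = 0.0654; 0 higher and 1 lower adjusted over the list alone). In all, 6974 of 13688 genes differed by limma with Benjamini-Hochberg adjustment, 3985 higher and 2989 lower in Duxbl-WT/Het embryos, and 3157 with a 2-fold minimum. The split was 4361 higher and 2320 lower with the values as deposited and 3592 and 3451 with median-of-ratios scaling. It turned to 3432 higher and 3565 lower with totals only and to 3795 higher and 4019 lower with no filter. Colony, collection and the unresolved mix of genotypes are confounded with these groups.

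Duxbl-KO embryos set against WT late embryos gave a further control for the knockout, which carries that same background. Colgalt2 (90.3 ± 45.6 CPM, n = 5), Adcy2 (71.7 ± 19.7 CPM) and Chl1 (18.1 ± 6.15 CPM) were present in Duxbl-KO embryos and listed at 0 in all 6 WT late embryos. Chit1, a chitinase, rose to 59.2 ± 34.8 CPM (5.58, SE 0.40, limma adjusted p = 1.1e-07) and Fam124a from 10.6 ± 16.1 to 107 ± 46.9 CPM (4.23, SE 0.72, limma adjusted p = 0.0013). Cacna1s was lower (-7.19, SE 0.27, limma adjusted p = 2.7e-11), as was Arsk, a sulfatase (-4.999, SE 0.40, limma adjusted p = 3.9e-07), and Pramel27, Kcnk18 and Pdgfrl were listed at 0 in all 5 Duxbl-KO embryos against 74.4 ± 22.9, 32.4 ± 10.4 and 26.2 ± 6.83 CPM in WT late embryos. Of predicted or clone-named genes, 2 with larger rises and 2 with larger falls were left out.

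Of 37 2-cell genes 18 were higher and 2 lower in Duxbl-KO than in WT late embryos (24 and 2 adjusted over the list alone). The median was 0.92 (camera adjusted p = 1.5e-07, adjusted p = 0.204 with an estimated correlation). Ribosome biogenesis genes were higher in 27 and lower in 0 of 50 cases (44 and 0 adjusted over the list alone). The median was 0.88 (camera adjusted p = 1.6e-12, adjusted p = 0.341 with an estimated correlation). Ribosomal protein genes were higher in 29 and lower in 0 of 76 cases (47 and 0 adjusted over the list alone). The median was 0.78 (camera adjusted p = 1.6e-12, adjusted p = 0.341 with an estimated correlation). Rpl21 stood at 1.31. Maternal transcripts were lower in 12 and higher in 1 of 51 cases (18 and 1 adjusted over the list alone). The median was -0.62 (camera adjusted p = 5.9e-08, adjusted p = 0.341 with an estimated correlation). Histones were higher in 8 and lower in 2 of 44 cases (10 and 2 adjusted over the list alone). The median was 0.54 (camera adjusted p = 0.0189, adjusted p = 0.341 with an estimated correlation). H4c14 stood at 1.74.

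The other lists were not called by camera between Duxbl-KO and WT late embryos. Trophectoderm and primitive endoderm markers were higher in 2 and lower in 6 of 13 cases (3 and 7 adjusted over the list alone; camera adjusted p = 0.0555), with Gata2 at -2.17 and Tfap2c at 1.14. Obox genes were higher in 2 and lower in 2 of 9 (3 and 2 adjusted over the list alone; camera adjusted p = 0.921). Pluripotency genes were higher in 0 and lower in 1 of 19 (0 and 0 adjusted over the list alone; median -0.01, mean -0.03, camera up, adjusted p = 0.921). DNA replication genes were higher in 3 and lower in 0 of 32, the same adjusted over the list alone (camera adjusted p = 0.0655). G2 and mitosis genes were higher in 3 and lower in 1 of 34 (2 and 1 adjusted over the list alone; camera adjusted p = 0.0555). Stress genes were higher in 2 and lower in 1 of 18, the same adjusted over the list alone (camera adjusted p = 0.311). Genes of the p53 list were higher in 2 and lower in 1 of 24 (0 and 1 adjusted over the list alone; camera adjusted p = 0.860). Chromatin silencing genes were higher in 6 and lower in 4 of 38 (7 and 4 adjusted over the list alone; camera adjusted p = 0.748), with Cbx1 at -2.22. Of markers of other cells Odf2 was lower (-0.97, limma adjusted p = 0.0130), Epcam higher (1.017, limma adjusted p = 0.0428) and Foxj1 did not pass (-0.38, limma adjusted p = 0.671). By limma with Benjamini-Hochberg adjustment 2419 of 11979 genes differed, 1254 higher and 1165 lower in Duxbl-KO embryos. The split was 1263 higher and 815 lower with the values as deposited, and it turned to 771 higher and 857 lower without Duxbl-KO replicate 5. The count was 1095 without Duxbl-KO replicate 1, 1397 and 1550 without WT late replicates 5 and 6, 3894 with all 4 groups in a single fit and 1535 with a 2-fold minimum.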

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

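The rule behind the values here was fixed before the data were examined: in a group of 4 to 10 embryos, a highest or lowest value whose distance to the next is a large part of the group's range (Dixon's criterion at 95%). Of 204 groups of values tested, 19 met it, with 9 in WT early, 6 in WT late and 4 in Duxbl-KO embryos. No explanation was tested for them. About 10.2 would meet it by chance if values were independent and normally spread. Levels of low genes in the same embryos are not, so the 19 cannot be judged against that figure. A gene above 0 in a single embryo of a group meets the rule by construction. WT late replicate 1 had 2828104 normalised reads, the highest of its group. The pluripotency list had a mean log2 level of 6.87 in Duxbl-KO replicate 3, above the next value of 6.61. The ribosomal protein list had a mean log2 level of 4.10 in WT early replicate 6, above the next value of 3.69, and the same embryo had the highest Rgs2 level, 983 CPM. Duxf3 was at 1.15 CPM in Duxbl-KO replicate 2 and listed at 0 in the other Duxbl-KO embryos. WT early replicate 5 had the highest values of 5 genes that rise by the late stage or in Duxbl-KO embryos, with 0.664 CPM for Tdpoz4, 0.996 CPM for Eif1ad4, 5.64 CPM for Eif1ad15, 5.98 CPM for Zscan4c (5.975 unrounded) and 0.664 CPM for Eif1ad3. Pramel19 reached 5.98 CPM (5.982 unrounded) in WT early replicate 3 and Rps3a3 2.48 CPM (2.485 unrounded) in WT early replicate 7. In WT late embryos, Ftdc1 was at 30.7 CPM and Fam124a at 37.2 CPM in replicate 2, Mmut at 1.26 CPM in replicate 3, Eif1ad4 at 19.6 CPM (19.65 unrounded) in replicate 1 and Chit1 at 0.764 CPM in replicate 6, where the other 5 embryos were listed at 0. In Duxbl-KO embryos, Nt5c was at 1.25 CPM in replicate 4 and Cacna1s at 0.681 CPM (0.6815 unrounded) in replicate 5, the latter listed at 0 in the others.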

How the results depend on the processing

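Chosen after the data were seen were the scaling as deposited, the pseudocounts of 0.25 and 4 CPM, robust empirical Bayes, array quality weights, the fits without genes of chromosomes X and Y and the index without 2-cell genes. Methods that need raw counts, namely the Wald test of DESeq2, the robust count fit, voom with quality weights and thinning to the smallest total, were not run. Of the values for the 4 gene counts, the stage index and the correlation, 156 stayed, 16 moved and 1 became stronger, where a count moved beyond 1.5 times, the index by crossing its threshold and the correlation by more than the SD of its values without each Duxbl-KO embryo. Of the values for single genes and lists, 2426 stayed, 43 lost and 32 gained a call, and 3 reversed, all 3 for Duxbl1 between stages (0.063 with median-of-ratios scaling, 0.20 with totals only, and -0.27 to 0.0097 over the fits without a library, the highest without WT late replicate 2). Leaving out each library gave 8801 to 9635 genes in the stage comparison, 1166 to 2532 for Duxbl-KO against Duxbl-WT/Het, 6081 to 7234 for Duxbl-WT/Het against WT late and 1095 to 3234 for Duxbl-KO against WT late. Leaving out each of the 27 crossed embryos gave a stage index difference of 0.13 to 0.23, and leaving out each of the 5 Duxbl-KO embryos a correlation of 0.12 to 0.19. A 2-fold minimum left 1065, 3157 and 1535 genes in the last 3 comparisons, by construction. Array quality weights gave 3108 genes for Duxbl-KO against Duxbl-WT/Het, all 4 groups in one fit 3894 for Duxbl-KO against WT late, 200 stage genes each way an index difference of 0.34 (exact permutation p = 0.0231), and Spearman in place of Pearson a correlation of 0.065; the cause was not tested. Replicate numbers did not pair the embryos: same-numbered embryos correlated from -0.30 to 0.17 in their deviations, and their own number fitted best in at most 1 case per comparison. With the replicate number as a block, 8644 genes were called between stages, 1697 for Duxbl-KO against Duxbl-WT/Het, 4448 for Duxbl-WT/Het against WT late and 1175 for Duxbl-KO against WT late. Of simulated 2-fold changes, 20.8% were called for Duxbl-KO against WT late, the comparison with the fewest embryos, and the part that depth has in this was not tested.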

Other observations

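Of the tests in this part, the range test of the near-absent genes, the account of the Duxbl1 neighbours and the values of single embryos were chosen after the results were seen. The genes around Duxbl1 on chromosome 14 were lower in Duxbl-KO than in Duxbl-WT/Het embryos more often than genes elsewhere. Of 17 tested genes starting within 1 Mb of Duxbl1, 5 were lower and 0 higher by limma, Zmiz1 (-1.38), Anxa11 (-1.42), Plac9a (-1.46), Gm18578 (-1.31) and Slmap (-0.54), a share of 29.4% against 8.61% of all tested genes. Of 12662 windows of the same width around other genes, each with at least 5 tested neighbours, 245 (1.93%) held as high a share. Windows of nearby genes overlap, so this is not a chance rate over independent regions. Duxbl-WT/Het replicate 9 stood apart from its group, with a mean log2 level of 6.32 for the 2-cell list (next highest 5.68), within the range of the Duxbl-KO embryos, Zscan4 copies at 401 CPM and Eif1ad copies at 800 CPM. Its Duxbl1 level was 134 CPM, against at most 35.2 CPM in Duxbl-KO embryos. Without it, 2532 genes were called between Duxbl-KO and Duxbl-WT/Het embryos.

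Random splits of the same embryos bear on whether chance gave the counts of genes, 100 per comparison with the real split among them. In each of the 4 comparisons only 1 split, the real one, gave as many genes, and 1 of 100 is the smallest share possible here. A chance division of these embryos is therefore unlikely to have given the counts. The splits cannot tell genotype or stage from litter or collection, which may differ between the groups. The counts were 9105 against at most 6750 between stages, 1931 against at most 99 for Duxbl-KO and Duxbl-WT/Het, 6974 against at most 4582 for Duxbl-WT/Het and WT late, and 2419 against at most 352 for Duxbl-KO and WT late. For the correlation of stage and knockout fold changes chance cannot be excluded, since 37 of 100 splits gave an absolute r as large as the real 0.16, the highest other being 0.37.

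The higher 2-cell genes of Duxbl-KO embryos were weighed against technical and developmental explanations. Lower sequencing depth of the Duxbl-KO libraries is argued against, since with estimated reads as a covariate the median log2 fold change of the list was 1.74, against 1.98 without it in the same 23 libraries. With the stage index, 2-cell genes left out, as a covariate the median was 1.89 (1.885 unrounded), against 1.98 in the same 27 embryos. This argues against a different point between WT early and WT late as the whole cause. The index rests on WT embryos at 32 h and 48 h, so it cannot place embryos beyond the late point. A few embryos do not carry it, because leaving out any 2 of the 5 Duxbl-KO embryos left a median of 1.64 to 2.11. A point later than WT late, genotype, litter, collection and reads shared between near-identical copies stay open and were not tested apart. The Duxbl-WT/Het embryos themselves lay below WT late embryos (median -1.19, 20 of 36 genes lower and 7 higher). Duxbl-KO embryos exceeded WT late embryos by a median of 0.92. Both calls were lost with an estimated correlation (camera adjusted p = 0.481 and 0.204).

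Cacna1s, Pramel27, Colgalt2 and the pseudogene Gm44988, the last named after its values were seen, were under 1 CPM in every embryo of either the 27 crossed or the 6 WT late embryos and at 10 CPM or more in every embryo of the other. Having the crossed embryos at another point of the WT early-to-late course was weighed as an account of this. Of these 4 genes, 2 change between WT stages in the direction of the cross difference, Pramel27 (-1.69) and Gm44988 (-1.76). Cacna1s (2.41) goes the other way, and Colgalt2 was too low in WT embryos to be tested between stages. So few genes leave it undecided. For 4 of 4 genes all crossed embryos lay outside the range of all 14 WT embryos. Separation from the 6 WT late embryos was fixed by how the genes were chosen, so only the WT early values could vary. Those lay on the same side of the crossed embryos as WT late. This would argue against a point between WT early and WT late only for genes whose level moves steadily between them, which 2 time points cannot show. Colgalt2, near 0 at both WT points, could have peaked in between. The range test therefore does not decide this, and it does not place the embryos as a whole. A point in between stays open, as do a later point and variants of the parents' colony, which were not tested.

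The broad difference between Duxbl-WT/Het and WT late embryos was set against the WT stage axis. With the WT late embryos split 3 and 3 between both comparisons, the correlation across 11556 genes had a median of 0.129 over 20 splits. It ran from -0.11 to 0.31. A shift along the axis between WT early and WT late may therefore account for a small part or none. This stays open because the highest split reached the limit set beforehand for the median, a limit applied to every split only after it was seen. The axis ends at 48 h, so this correlation cannot judge a point later than WT late, which also stays open. With the WT late embryos shared, r was 0.10 and the covariance 0.14, where simulated unchanged embryos gave -0.80 and -0.06. Colony, collection and the mixed genotypes cannot be told apart from the groups.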
